A study of Mus musculus with 4 samples.

How the data were processed

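Total RNA of DP cells was extracted with a column kit, and 100 ng were converted to biotin-labelled cRNA by 3' in vitro transcription and hybridized to Affymetrix Mouse 430 2.0 arrays, per the labels' protocols. The authors deposited 1 intensity per probe set and array, on a linear scale from 0.08 to 19270, for 45101 probe sets. RMA is named per the submitters' processing notes, with no version given. Values below 1 are unusual for RMA, so how the probes were summarised is not settled. In the deposited values, 77.7% of the sorted ranks lay within 1% of each other on all 4 arrays, so the arrays had been brought to nearly the same distribution. Detection calls were not used here. Quantile-type normalization assumes that most genes do not change and hides a shift common to all of them.

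Arrays were grouped by their titles, which give 2 normal thymus and 2 tumour samples, each numbered 1 and 2. The sample type label describes all 4 samples as tumour cells, against the title, source and genotype labels of the 2 normal ones. Before the data were examined, the groups, the test, the gene lists, the rule for named genes and most alternatives were fixed. The design was written for log2 values, taking log2 first where the file is linear, and log2 was taken here with no offset and no filter on dim probe sets.

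Probe sets were named from the GEO platform annotation. Of 45037 probe sets that are not controls (64 controls were left out of the tests), 34945 had 1 gene symbol, 932 had several and 9160 had none. Only probe sets with 1 symbol were used for genes. Symbols were checked through Entrez numbers against the RefSeq table of GRCm38.p6, where 18032 of 18193 genes matched and 0 symbols changed. That table was used for names and chromosomes only, and no coordinates are given because no build is named in the sources used here. Each gene was represented by its probe set with the highest mean over the 4 arrays. Of 9010 genes with several probe sets, 388 had probe sets called in opposite directions with the trend and robust prior, 13 of them among the genes called by the main design, and of the named genes Aebp2 and Ikzf2.

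Differences were tested with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3 on all 4 arrays, with no covariate, and adjusted by Benjamini-Hochberg over 18193 genes at a threshold of 0.05. Residual degrees of freedom were 2 and the prior added 0.989, against 7.23 (median) with the trend and robust prior. The replicate SD (log2) had a median of 1.31 in the dimmest 25% of genes and 0.084 in the brightest 25%. In data simulated on these genes with 200 changed among those with a mean log2 of at least 7, the main design recovered 0% of genes changed by 1 or 2 (log2) and 69.7% of those changed by 4, and the trend and robust prior recovered 58.2%, 85.1% and 98.5%, with 4 false calls each. With 2000 genes changed by 2, the shares were 95.3% and 98.4%, with 134 and 74 false calls.

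The 33 gene lists held 539 measured genes, and the 32 with at least 5 measured members were tested with camera at an inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the lists. Chromosomes 1 to 19 and X were tested in the same way. List members carried by unnamed or shared probe sets were not analysed here. Some list members stand in more than 1 list, among them 12 of 22 early progenitor genes and 8 of 24 maturation genes. Many markers were above background in normal DP arrays too, among them 9 of 14 macrophage, 7 of 12 neutrophil, 8 of 11 dendritic and 8 of 12 NK markers.

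Named genes were the 10 highest and 10 lowest log2 fold changes among called genes whose arrays did not overlap between groups, with a mean log2 of at least 7 in the higher group, a probe set not of the _x_at class (the _s_at class, which may also bind other transcripts, was allowed) and a symbol that is not a clone number, then Notch1, Hes1, Dtx1, Myc, Ptcra, Il2ra, Cd4, Cd8a and Ezh2, and per list up to 4 called members with the largest change, or 2 where none was called. Chance alone keeps the groups of a gene apart in 33.3% of splits of 2 against 2.

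The background level of an array was its highest value among 27 control probe sets for bacterial genes without spike signal. Where both arrays of a group lay at or below it on the probe set that represents the gene, the fold is given as "at least N-fold", the mean of the other group over the dim group's mean with each array raised to its background level, and no fold is given where both groups lay there. Spike scaling shifts each array to the same mean over 14 BioB, BioC and BioD control probe sets.

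Alternatives fixed in advance were median subtraction, renewed quantile normalization, leaving out probe sets below the 30th or 50th percentile of mean level, the trend and robust prior, a fold minimum, a threshold of 0.01, the mean of a gene's probe sets, leaving out probe sets that may bind other transcripts, the replicate number as a block and leaving out each array. Added after seeing the data were an offset of 16, raising values to background, spike scaling, and the trend and robust prior together with the block or with an array left out. Figures were drawn with matplotlib 3.10.9.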

Results

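Gene expression was measured on 4 Affymetrix Mouse 430 2.0 arrays, with RNA from CD4+CD8+ double-positive (DP) T-lineage cells of C57BL/6 mice. DP cells are the immature thymocytes that carry both co-receptors. Of the 4 arrays, 2 held DP cells of normal thymus and 2 held DP cells of peripheral tumours (thymoma) that over-express Notch1-IC. Notch1-IC is the intracellular and active part of the Notch1 receptor. The tumours are from a mouse model of T-cell acute lymphoblastic leukaemia (T-ALL). Between 51.0% and 59.0% of the probe sets on an array lay above its background level, which ranged from 12.3 to 17.8 intensity units. Across the 6364 genes with a mean log2 intensity of at least 7, the arrays of a group correlated at r = 0.991 (normal) and r = 0.991 (tumour), and arrays of different groups at 0.816 to 0.822. These correlations are across genes, which are not independent replicates. The median absolute log2 difference over the same genes was 0.115 between the normal arrays, 0.104 between the tumour arrays and 0.458 to 0.473 between groups. Nothing in the labels says that the arrays of a group came from separate animals. Limma's p-value for a gene or probe set thus measures only the spread between these samples, which may be technical. Camera with a fixed correlation, the permutation of genes over lists and the gene family tests take their spread from genes instead. Small p-values of those tests are not evidence from replicate animals. The number of arrays limits the precision. Scan dates and batches are not given in the sources used here, so a batch that follows the groups cannot be told apart from them. The titles place the tumour cells in a peripheral tumour and the normal cells in thymus. Tissue site thus cannot be told apart from transformation.

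The comparison addressed which transcripts differ between DP cells of peripheral Notch1-IC tumours and of normal thymus. In the tumour cells, Notch1 and Notch targets such as Dtx1, Nrarp and Il2ra rose, as did Myc and some genes of ribosome production, glycolysis and amino acid supply, while Cd4, Cd8a and other genes of the DP stage and of the T-cell receptor (TCR) pathway fell. Dtx1, a regulator of Notch signalling, rose by 6.27 ± 0.14 on the log2 scale (SE, n = 2 arrays per group), a 77.4-fold difference, and Cd8a, a chain of the CD8 co-receptor, fell by 2.75 ± 0.13. Both tumour arrays lay on the same side of both normal arrays for these genes. Several transcripts known from macrophages and neutrophils, such as Csf1r and S100a8, also rose, and Xist, the RNA that silences an X chromosome, was at least 375-fold lower.

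With limma's moderated test, 759 of 18193 genes rose and 401 fell at an adjusted p below 0.05. The median log2 fold change was 2.33 among the genes that rose and -1.99 among those that fell, and all 1160 differed by at least 2-fold. The smallest adjusted p was 0.0338, and 3252 genes were higher and 2306 lower at an unadjusted p below 0.05. Of the genes that rose, 200 had every probe set at or below background on both normal arrays, of those that fell 105 on both tumour arrays, and 110 of the 1160 on all 4 arrays. Limma's trend and robust prior, which lets the variance prior follow the level of expression and also limits the influence of outlying variances, gave 3156 higher and 2251 lower genes, with 1023 of the 1160 shared. Leaving out any single array left 0 of the 1160 calls under the design chosen in advance, against 2269 to 2669 higher and 1609 to 1868 lower genes with the trend and robust prior. The share of higher among all changed genes was 65.4%. It was 20.9% (650 higher and 2456 lower genes) when the arrays were scaled to the bacterial BioB, BioC and BioD hybridization controls, which lay 0.60 higher (log2) in the tumour arrays, mainly through the larger number of lower genes. Single probe sets of these controls shifted by 0.28 to 0.91, so scaling all genes by the mean shift is approximate. The 4 Cre hybridization controls, more intense still, differed by -0.08 to 0.03, though a shift may be partly hidden near the maximum that all 4 arrays share. That scaling moved the median of all genes from 0.088 to -0.51. Tested over all 45037 probe sets without reference to genes, limma gave 0 changed probe sets, with 11337 at an unadjusted p below 0.05 and 10273 past the threshold with the trend and robust prior.

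Of 23 measured Notch pathway genes and targets, 10 rose and 1 fell, with a median log2 fold change of 1.40 (0.91 with dim genes at their bounds). Notch1, over-expressed in part by the model, is itself a list member and counts among the genes that rose. The median was 0.73 with the mean of probe sets and 0.80 with spike scaling. Adjusted over the list alone, 15 rose and 2 fell. Notch1 itself rose by 2.62 ± 0.14 (limma adjusted p = 0.0338), a 6.15-fold difference. The probe set lies on the transcript of Notch1, and whether it also detects the introduced Notch1-IC sequence is not known. Hes1, a transcriptional repressor induced by Notch, was at or below background on both normal arrays and at least 34.8-fold higher in the tumour arrays (adjusted p = 0.0448). Nrarp, a feedback inhibitor of Notch, rose by 5.07 ± 0.17 and Il2ra, the interleukin 2 receptor alpha chain, by 5.86 ± 0.16 (both with adjusted p = 0.0338). Ptcra, the pre-TCR alpha chain, rose by 1.72 ± 0.13 (adjusted p = 0.0392). The list as a whole shifted up against all other genes (limma camera with a fixed correlation, adjusted p = 7.73e-06). It did not pass in camera with the correlation estimated from these arrays (adjusted p = 0.285). That estimate was -0.017, below the fixed value, so higher correlation between the genes does not account for the loss. Why the 2 forms of camera differ was not tested.

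**Figure D1:**
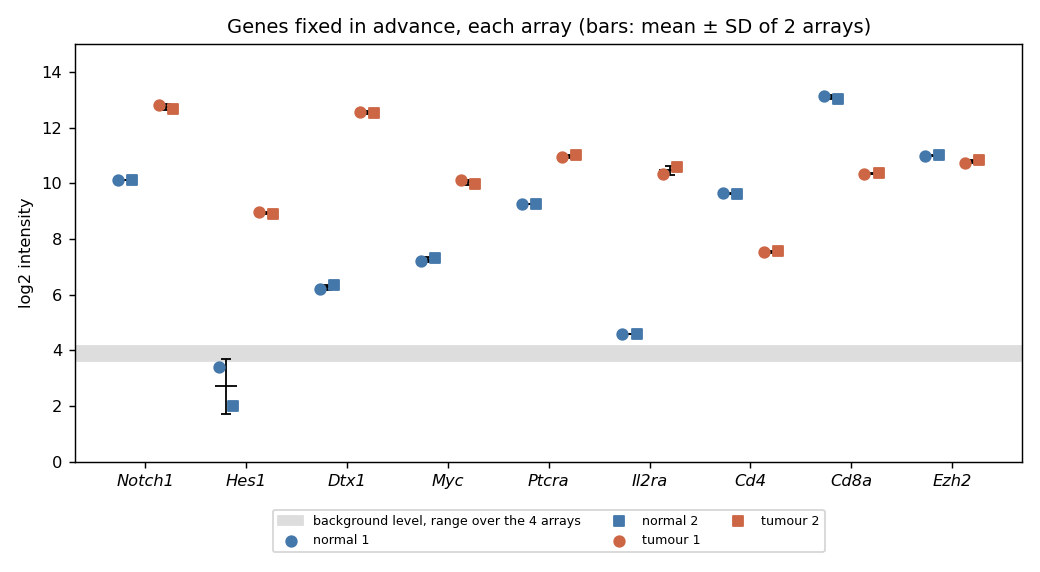
The vertical axis gives log2 intensity for 9 genes fixed in advance, with points for each of the 4 arrays, black bars for the mean and SD of the 2 arrays per group, and a grey band for the range of the background level. Hes1 lies at or below background in both normal arrays, and from normal to tumour Dtx1 differs by 6.27, Cd8a by -2.75 and Ezh2 by -0.21 (log2).

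Myc, a transcription factor that drives growth, rose by 2.77 ± 0.15 (limma adjusted p = 0.0338), a 6.84-fold difference. Of 25 measured MYC targets and ribosome biogenesis genes, 7 rose and 0 fell, and 21 rose when adjusted over the list alone. The largest rises were those of Tfrc, the transferrin receptor (2.71 ± 0.13), Apex1, a DNA repair enzyme (2.53 ± 0.14), Cad, which starts pyrimidine synthesis (2.52 ± 0.13), and Mybbp1a, a nucleolar protein (2.18 ± 0.13). The probe set of Apex1 is of a kind that may bind other transcripts, and without such probe sets Apex1 differed by 1.64. The list's median was 1.01 (camera adjusted p = 1.2e-08, and adjusted p = 0.285 with an estimated correlation), and 0.41 with spike scaling. With the trend and robust prior, 23 of the 25 passed, all higher.

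Some glycolysis and amino acid genes rose too. Of 18 measured glycolysis genes, 4 rose and 0 fell, or 11 and 1 adjusted over the list alone. They were Aldoc (2.26 ± 0.24, with 1 of the 2 normal arrays at or below background), the glucose transporter Slc2a3 (1.96 ± 0.20), Tpi1 (1.92 ± 0.15) and Pkm, the pyruvate kinase (1.69 ± 0.13). Without probe sets that may bind other transcripts, Slc2a3 differed by 0.65 (adjusted p = 0.768). The list's median was 0.80 (camera adjusted p = 0.000769, and adjusted p = 0.285 with an estimated correlation), and 0.20 with spike scaling. Among 20 genes of amino acid supply and the ATF4 response, 8 rose and 0 fell, or 10 and 1 adjusted over the list alone. Slc7a5, a transporter of large neutral amino acids, rose by 3.39 ± 0.14, a 10.5-fold difference. Shmt2, an enzyme of serine use in mitochondria, rose by 2.35 ± 0.13, and the transcription factors Cebpb and Atf5 by 2.29 ± 0.15 and 2.12 ± 0.15. Shmt2 rose by 1.40 without probe sets that may bind other transcripts. This list had a median of 1.28 (camera adjusted p = 0.00794, and adjusted p = 0.285 with an estimated correlation), and its camera call ended without tumour replicate 1 (adjusted p = 0.0612). Of 18 genes of cholesterol synthesis, 4 rose and 0 fell, or 6 and 2 adjusted over the list alone. Idi1 rose by 1.82 ± 0.13, Cyp51 by 1.74 ± 0.13 and Hmgcs1 by 1.34 ± 0.14. Hsd17b7 rose by 1.69 ± 0.18 on a probe set that may bind other transcripts, and by 0.36 without such probe sets, where it did not pass (adjusted p = 0.512). The cholesterol list's median was 0.54 (camera adjusted p = 0.0193, and adjusted p = 0.293 with an estimated correlation). Its call ended at a threshold of 0.01, without normal replicate 1 (adjusted p = 0.0935), without normal replicate 2 (adjusted p = 0.0572) and without probe sets below the 50th percentile of level (adjusted p = 0.0551). It also ended with the mean of probe sets (median 0.28, adjusted p = 0.191), without probe sets that may bind other transcripts (median 0.34, adjusted p = 0.0557) and with spike scaling (median -0.06, adjusted p = 0.165).

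Of 22 measured members of the DP thymocyte programme, 10 fell and 0 rose, or 15 and 1 adjusted over the list alone. Cd8a fell by 2.75 ± 0.13 (limma adjusted p = 0.0338) and Cd8b1, the other CD8 chain, fell by 2.19 ± 0.16 (adjusted p = 0.0386). Cd4 fell by 2.09 ± 0.13 (adjusted p = 0.0354), a 4.26-fold difference, and Rag2, which cuts DNA for receptor rearrangement, fell by 1.92 ± 0.17 (adjusted p = 0.0438). The list's median was -1.24 (camera adjusted p = 5.64e-06, and adjusted p = 0.285 with an estimated correlation). Among 23 genes of TCR signalling, 7 fell and 1 rose, or 10 and 2 adjusted over the list alone. The log2 fold changes were -2.66 ± 0.13 for Sla, an adaptor that lowers TCR levels, -2.52 ± 0.13 for Cd247, the CD3 zeta chain, -2.45 ± 0.17 for Cd5, an inhibitory receptor, and -1.58 ± 0.14 for Cd6. The TCR list's median was -0.45 (camera adjusted p = 8.66e-05, and adjusted p = 0.285 with an estimated correlation), and -1.05 with spike scaling. In the same arrays the ratio of 3' to 5' control probe sets was higher in the tumour samples, at 2.49 ± 0.050 against 1.24 ± 0.056 for beta-actin (SD, n = 2).

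**Figure D2:**
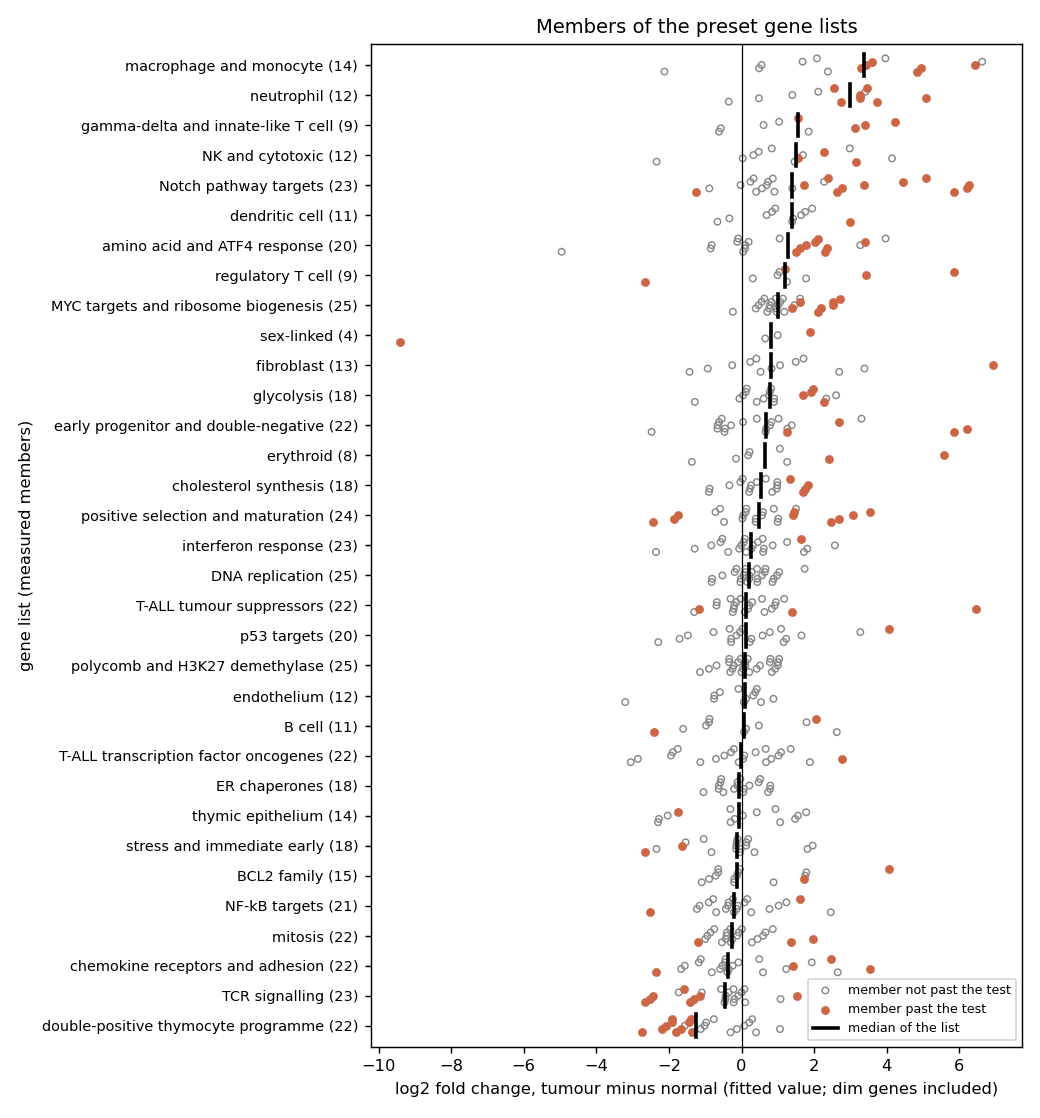
Each row is a gene list fixed in advance, with the number of measured members in parentheses, and the horizontal axis gives the log2 fold change of tumour minus normal. Filled points are members past limma's threshold, open points are the others, and black bars are list medians, from -1.24 for the DP thymocyte programme to 3.36 for the macrophage and monocyte markers. Fitted values of genes at or below background are not bounds.

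The largest rises were of mixed kinds. Among genes chosen by the naming rule, Ifi202b, an interferon-inducible gene, was at least 104-fold higher, Chil3, a chitinase-like protein of macrophages, at least 82.1-fold and Lgals7, galectin 7, at least 50.9-fold. Arg1, the arginase of liver and some macrophages, was at least 25.5-fold higher, Exoc3l4 at least 23.8-fold, Khdc1a at least 15.6-fold, Adamts20 at least 12.7-fold and Cd163, a scavenger receptor of macrophages, at least 11.7-fold. For these, both normal arrays lay at or below background on every probe set. Susd4 was at least 60.2-fold higher on its most intense probe set, and another lay above background on 1 normal array. Limma's adjusted p lay between 0.0338 and 0.0446 over these genes. Adam19, a membrane metalloprotease, was above background in both groups and rose by 7.45 ± 0.19, a 175-fold difference. Macrophage and monocyte markers as a list had a median of 3.36 in the same arrays.

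The largest falls were led by Xist. Its most intense probe set had a mean log2 intensity of 12.49 in the normal arrays and lay at or below background on both tumour arrays (limma adjusted p = 0.0338). Eif2s3y, a gene of the Y chromosome, rose by 1.89 ± 0.17 (adjusted p = 0.0438). Sik1, a kinase, was at least 8.79-fold lower. On their most intense probe sets Rab6b was at least 17.4-fold and Slc15a2, a peptide transporter, at least 15.1-fold lower, but other probe sets of both lay above background on 1 tumour array, with log2 fold changes of -2.69 and -4.01 for Rab6b and 0.48 for Slc15a2. The log2 fold change was -6.08 ± 0.14 for Dgkeos, -4.81 ± 0.25 for Dleu2, -4.78 ± 0.47 for Tdrp, -4.43 ± 0.35 for Unc5cl, -4.38 ± 0.25 for Cdc42ep3 and -4.31 ± 0.29 for Insl5, with limma adjusted p between 0.0338 and 0.0454 over the 10 genes. For Dleu2, Tdrp and Insl5, 1 of the 2 tumour arrays lay at or below background. Dgkeos lay just above it on tumour replicate 1 (4.23 against 4.15, log2), and its other probe set gave -4.22. Of the 4 measured sex-linked genes, 1 rose and 1 fell, also when adjusted over the list alone, and so small a list was not tested as a whole.

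Markers of other blood cells were measured beside these groups. Of 14 macrophage and monocyte markers, 6 rose and 0 fell, or 9 and 0 adjusted over the list alone. C1qa, a complement subunit, was at least 16.3-fold higher and Fcgr3, an Fc receptor, at least 13.1-fold. Csf1r, the receptor for the macrophage growth factor, rose by 4.94 ± 0.17 and C1qb by 3.61 ± 0.27. The list's median was 3.36 (3.14 with dim genes at their bounds), with camera adjusted p = 4.87e-05 and adjusted p = 0.285 with an estimated correlation. Of 12 neutrophil markers, 7 rose and 0 fell, the same numbers as adjusted over the list alone, with a median of 3.0 (2.03 with dim genes at their bounds). S100a8 rose by 3.72 ± 0.23 and the protease Mmp9 by 3.46 ± 0.39 (1 of the 2 normal arrays at or below background), while Lcn2 was at least 5.88-fold and Ltf at least 2.85-fold higher. The neutrophil list gave camera adjusted p = 0.000596 and adjusted p = 0.285 with an estimated correlation. Of 11 dendritic cell markers, 1 rose and 0 fell, or 5 and 0 adjusted over the list alone. That member was H2-Aa, an MHC class II chain (2.98 ± 0.29). The dendritic list's median was 1.40 (0.93 with dim genes at their bounds), with camera adjusted p = 0.0213 and adjusted p = 0.295 with an estimated correlation. Its call ended at a threshold of 0.01, without normal replicate 1 (adjusted p = 0.100), without tumour replicate 2 (adjusted p = 0.0573) and without probe sets that may bind other transcripts (median 0.89, adjusted p = 0.115), the only kind measured for H2-Aa.

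Markers of other lymphocyte types rose in part. Of 12 NK and cytotoxic genes, 3 rose and 0 fell, or 5 and 0 adjusted over the list alone. They were the granzymes Gzmb (3.15 ± 0.20) and Gzma (2.28 ± 0.13) and the granule protein Nkg7 (1.55 ± 0.15). The median was 1.51 (1.15 with dim genes at their bounds), with camera adjusted p = 0.00794 and adjusted p = 0.285 with an estimated correlation. Among 9 markers of gamma-delta and innate-like T cells, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. Cd163l1 rose by 4.24 ± 0.18 (1 of the 2 normal arrays at or below background), Trgv4, a gamma chain variable segment, by 3.41 ± 0.15, and the transcription factors Maf and Etv5 by 3.12 ± 0.20 and 1.57 ± 0.15. This list had a median of 1.57, with camera adjusted p = 0.0177 and adjusted p = 0.407 with an estimated correlation. The gamma-delta call ended at a threshold of 0.01, without normal replicate 1 (adjusted p = 0.102) and without tumour replicate 2 (adjusted p = 0.0580). Of 9 regulatory T cell markers, 3 rose and 1 fell, or 5 and 1 adjusted over the list alone. Il2ra, also a Notch list member, rose as given above, Ctla4, an inhibitory receptor, rose by 3.43 ± 0.18, and Tnfrsf18 fell by 2.65 ± 0.14. Ikzf2 rose by 1.21 ± 0.14 on its most intense probe set, whereas the mean of its probe sets gave -0.92. The regulatory T cell list had a median of 1.21 (1.05 with dim genes at their bounds), with camera adjusted p = 0.00853 and adjusted p = 0.285 with an estimated correlation. Its call ended with the mean of probe sets (median 0.99, adjusted p = 0.0801).

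The remaining marker lists did not pass in the design chosen in advance. Of 11 B cell markers, Pou2af1 rose by 2.05 ± 0.16 and Cd79b fell by 2.42 ± 0.18, or 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.939). The B cell list had a median of 0.07 and a mean of 0.03, while camera placed it below the other genes. Of 8 erythroid genes, Alas2 was at least 5.97-fold and Epor at least 1.56-fold higher, and 3 rose adjusted over the list alone (median 0.64, camera adjusted p = 0.167, and 0.0242 with spike scaling). Of 13 fibroblast markers, 1 rose, also when adjusted over the list alone. It was Pdgfrb, a growth factor receptor, by 6.92 ± 0.16, a 121-fold difference (list median 0.83, or 0.38 with dim genes at their bounds, camera adjusted p = 0.0874). The fibroblast list passed without normal replicate 2 (adjusted p = 0.0203) and with spike scaling (adjusted p = 0.00585). Epcam was the only one of 14 thymic epithelium markers past the threshold over all genes and fell by 1.76 ± 0.17, with 4 higher and 3 lower adjusted over the list alone (median -0.08, camera adjusted p = 0.770). Among 12 endothelium markers 0 passed limma's threshold, also adjusted over the list alone. Egfl7 differed by 0.88 ± 0.15, Tie1 was at or below background on all arrays, and 1 passed with the trend and robust prior. The endothelium list's median was 0.10, its mean was -0.22 and camera placed it below the other genes (adjusted p = 0.939).

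The cell division genes did not pass as lists. Among 25 genes of DNA replication, 0 passed limma's threshold, over all genes or adjusted over the list alone, while 11 were higher and 3 lower with the trend and robust prior. Mcm2, a helicase subunit, differed by 1.74 ± 0.28 (adjusted p = 0.0664), or by 0.19 without probe sets that may bind other transcripts, and E2f1 by 1.04 ± 0.23 (adjusted p = 0.101). The list's median was 0.22 (camera adjusted p = 0.0874, and 0.0123 with the trend prior) and -0.38 with spike scaling. Of 22 mitosis genes, Mki67, a marker of cycling cells, rose by 1.97 ± 0.16, Cenpe rose by 1.37 ± 0.13 and Kif20a fell by 1.19 ± 0.13, with 5 higher and 6 lower adjusted over the list alone. The mitosis median was -0.27 (camera adjusted p = 0.208), and the list passed with spike scaling (adjusted p = 0.0482) and without probe sets that may bind other transcripts (adjusted p = 0.0258).

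Thymocyte stage genes outside the DP programme moved both ways. Of 24 genes of positive selection and maturation, 6 rose and 3 fell, or 11 and 3 adjusted over the list alone. Itgae, an integrin chain, rose by 3.55 ± 0.27 on a probe set that may bind other transcripts, and its other probe set gave 1.08 and did not pass (adjusted p = 0.106). Klf2, which controls thymic exit, rose by 3.06 ± 0.18, Il7r by 2.69 ± 0.13 and S1pr1, the receptor used for exit, by 2.46 ± 0.18. The median was 0.48 (camera adjusted p = 0.0519, 0.0136 with the trend prior and 0.0371 with an offset of 16) and -0.12 with spike scaling. Of 22 early progenitor and double-negative genes, 4 rose and 0 fell, the same numbers as adjusted over the list alone. They were Hes1, Il2ra, Il7r and Id1 (1.25 ± 0.13), and the list's median was 0.67 (0.10 with dim genes at their bounds, camera adjusted p = 0.167, and 0.0173 with spike scaling). Among 22 chemokine receptor and adhesion genes, 3 rose and 1 fell, or 4 and 4 adjusted over the list alone. Itgae, S1pr1 and Itgb7 (1.42 ± 0.14) rose and Icam2 fell by 2.36 ± 0.17. Their median was -0.37 and their mean 0.12, and camera placed the list lower (adjusted p = 0.283).

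Cell death and tumour suppressor genes were next. Of 15 BCL2 family genes, 2 rose, or 3 rose and 1 fell adjusted over the list alone. Pmaip1, which encodes the death promoter NOXA, rose by 4.05 ± 0.24, a 16.6-fold difference, and the death effector Bak1 by 1.72 ± 0.13. The family's median was -0.13 and its mean 0.37, and camera placed it lower (adjusted p = 0.940). Pmaip1 was also the only one of 20 p53 targets to rise, with 0 falling, or 4 and 3 adjusted over the list alone (median 0.13, -0.47 with spike scaling, camera adjusted p = 0.959). Of 22 T-ALL tumour suppressors, 2 rose and 1 fell, or 5 and 2 adjusted over the list alone. Cdkn2a, which encodes cell cycle inhibitors, was at least 12.1-fold higher, Ptpn2 rose by 1.39 ± 0.14 and Phf6 fell by 1.17 ± 0.13 (list median 0.13, -0.47 with spike scaling, camera adjusted p = 0.902). Of 22 T-ALL transcription factor oncogenes, Myc alone rose, over all genes and adjusted over the list alone, with a list median of -0.02, a mean of -0.16 and an upward camera direction (adjusted p = 0.981).

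The polycomb genes did not pass. Ezh2, the H3K27 methyltransferase, differed by -0.21 ± 0.13 (limma adjusted p = 0.395). Among 25 polycomb and H3K27 demethylase genes, 0 passed, also adjusted over the list alone, and 9 were higher and 2 lower with the trend and robust prior. Phf1 differed by -1.14 ± 0.46 and Aebp2 by 1.04 ± 0.14, and other probe sets of Aebp2 went the opposite way. The list's median was 0.10, or -0.50 with spike scaling (camera adjusted p = 0.579).

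The stress and immune signalling lists did not pass in that design either. Of 18 ER chaperones 0 passed limma's threshold, over all genes or adjusted over the list alone, with 6 higher and 6 lower under the trend and robust prior. Xbp1, a transcription factor of secretory cells, differed by -1.05 ± 0.14, or by -1.89 without probe sets that may bind other transcripts, and Hyou1 by 0.79 ± 0.22 (list median -0.07, camera adjusted p = 0.567, and 0.0470 with spike scaling). Of 18 stress and immediate early genes, Fos fell by 2.67 ± 0.25 and Dusp1 fell by 1.63 ± 0.13, and 1 rose and 5 fell adjusted over the list alone (median -0.12, camera adjusted p = 0.197, and 0.0405 with values raised to background). Among 21 NF-kB targets, Irf1 rose by 1.62 ± 0.16 and Nfkbiz fell by 2.53 ± 0.20, or 1 rose and 2 fell adjusted over the list alone (median -0.21, camera adjusted p = 0.364). Of 23 interferon response genes, Ifih1, a sensor of viral RNA, rose by 1.64 ± 0.16 and 4 rose adjusted over the list alone (median 0.27, -0.33 with spike scaling, camera adjusted p = 0.336).

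Several named genes had probe sets that differed in size. With the mean of all probe sets of a gene, dim ones included, 23 of 106 named genes moved by more than 1.5 times, and limma called 0 genes at that setting. The log2 fold change was then 2.98 for Dtx1, 1.31 for Tfrc, 1.14 for Cyp51, 1.47 for Cebpb, 1.94 for Maf, 0.97 for Etv5, 0.85 for Bak1 and 0.20 for Ptpn2. Among genes that fell it was -3.21 for Cd4, -1.51 for Cd247, -0.79 for Nfkbiz, -0.48 for Epcam, -3.78 for Rab6b, -2.76 for Dleu2, -2.74 for Sik1 and -0.97 for Slc15a2, and it was 0.01 for Hyou1. Ifi202b, S100a8 and H2-Aa had only probe sets that may bind other transcripts. Without such probe sets Xist differed by -8.59 (adjusted p = 0.0596) and C1qb by 3.46 (adjusted p = 0.187). Kif20a, Aldoc, Hmgcs1, Id1, Phf6, Mmp9 and Ikzf2 kept their probe sets and log2 fold changes at that setting, and their adjusted p moved just past the threshold (from 0.0514 to 0.0541). With spike scaling Cenpe, Hsd17b7, Hmgcs1, Id1, Ifih1, Ptpn2, Itgb7 and Ikzf2 no longer passed (adjusted p from 0.0510 to 0.0869). Epor did not pass with the trend and robust prior (adjusted p = 0.0541) or with values raised to background (adjusted p = 0.0995).

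In all, 13 of 32 tested lists passed camera's threshold with the fixed correlation, 11 higher and 2 lower. With the correlation estimated from the 4 arrays 0 passed, and the smallest adjusted p was 0.285. Among the 13 lists, the estimate exceeded the fixed value only for MYC targets (0.078), TCR signalling (0.033) and gamma-delta T cells (0.119). For the other called lists, higher correlation between genes thus does not account for the loss. All 13 lists were tested on only 2 residual degrees of freedom in the estimated form, against the number of genes in the fixed form. At an unadjusted p below 0.05, fry called 23 lists, which tests whether a list's genes move one way and does not compare it with other genes. Camera called 0 of 20 chromosomes, the smallest unadjusted p was 0.189 for the X chromosome, and all adjusted p were 0.981. Chromosome 15, which carries Myc, had a median of 0.122 over 724 genes, chromosome 18 of 0.211 over 459 genes and the X chromosome of -0.040 over 617 genes.

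**Figure D3:**
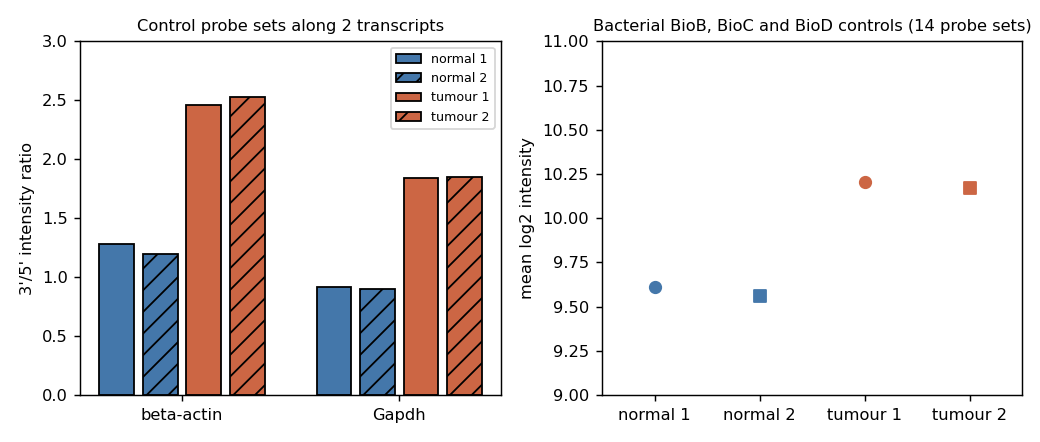
The left panel gives the ratio of 3' to 5' control probe set intensity of beta-actin and Gapdh on each of the 4 arrays, and the right panel the mean log2 intensity of 14 bacterial control probe sets. The ratios are 1.20 to 1.28 (beta-actin) and 0.897 to 0.912 (Gapdh) in the normal arrays against 2.46 to 2.53 and 1.84 to 1.85 in the tumour arrays, and the bacterial controls lie 0.60 higher.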

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

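The tests of macrophages as a source, of all 10 other marker lists and whether they moved apart, of the macrophage list and the higher genes against array scaling and of pooled sexes were chosen after the result was seen, and the signals of the control probe sets were noticed in the data.

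Some control probe sets, which enter no comparison of genes, differed between the groups. The 5' probe set of 18S ribosomal RNA was higher by 1.82 (log2) in the tumour arrays. The bacterial BioB, BioC and BioD controls were higher by 0.60 on average. Single probe sets ran from 0.28 on a BioD probe set (normal mean log2 11.4) to 0.91 on a dimmer BioB probe set (8.22). The shift was thus not the same at all intensities. The 4 Cre controls, with mean log2 of 13.5 to 14.2, differed by -0.08 to 0.03. They show no such shift, though a shift may be partly hidden near the maximum that all arrays share. The ratio of 3' to 5' probe sets was 2.49 for beta-actin and 1.85 for Gapdh in the tumour arrays, against 1.24 and 0.905 in the normal arrays.

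The control ratios raise the question whether the genes called lower in the tumour arrays reflect lower integrity of the tumour RNA. Further probe sets were counted only where they lay above background on both arrays of the group in which the gene was higher. Such probe sets existed for 167 genes called lower and 321 called higher. Of those of the lower genes, 65.2% were lower by at least 1 (log2), between the bounds set beforehand. For the genes called higher the share was 66.0%, and the same sign was seen in 92.9% and 93.4% of these probe sets. That choice of probe sets favours the same direction in advance. Lower RNA integrity and a change in the cells cannot be told apart for the lower genes. The 3' to 5' control ratios, only an indirect sign of integrity, differ with the group. Scaling to the BioB, BioC and BioD controls left 650 genes called higher, 602 of them among the 759. All 759 differed by at least 2-fold before scaling, above the controls' 1.52-fold, so this outcome was nearly fixed. It shows only that a common shift of that size is smaller than these differences.

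The macrophage and monocyte markers had a median log2 fold change of 3.36, which exceeded the shift of the BioB, BioC and BioD controls by 2.76. A common shift of that size is too small to be the whole cause, and other forms of scaling were not tested. A lower share of DP cells would raise all other cell types alike if the mix of those cells were the same in thymus and tumour. Whether it was the same was not tested. The medians of 6 other marker lists chosen beforehand centred on 0.37. This was far enough below the macrophage median to pass the bound set beforehand against that explanation. It is still not settled, since these lists include thymic epithelium, which a peripheral tumour need not hold, and members near background. The medians of all 10 other lists centred on 1.02, with 3.0 for neutrophils. Whether the other lists moved apart depended on the lists and members compared, with p below 0.05 in 6 of 9 choices (permutation of genes over lists, 100000 resamples, p from 0.00135 to 0.176) and in 4 of 9 after Benjamini-Hochberg adjustment (0.00972 to 0.176). Macrophages among the collected cells remain a candidate source, although selection for CD4 and CD8 should remove them. Another marker, Itgam, differed by -2.12 without passing the test. Lyz2, C1qb, Ctss and Csf1r lay above background on both tumour arrays, but C1qb and Csf1r did so on both normal arrays too. Their signal restates the rise and does not test its source. Expression of these genes by the tumour cells themselves was not tested and stays open.

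Xist was at least 375-fold lower in the tumour arrays, which may reflect the sex of the mice, which the sources used here do not give. All 3 measured Y-linked genes lay above background on both normal arrays and all 3 on both tumour arrays. Signal above background alone therefore cannot tell female normal and male tumour cells from loss of Xist in female tumours. Related X-linked genes may bind the same probes. Normal cells pooled from both sexes with tumour cells from males remain a candidate explanation, since the Y-linked genes had a median log2 fold change of 1.00. On their most intense probe sets all 3 were higher on both tumour arrays than on both normal arrays, by 1.89 (Eif2s3y), 1.00 (Uty) and 0.65 (Kdm5d). A dim probe set of Kdm5d gave -0.78. Loss of Xist in female tumours would not by itself raise Y-linked genes. The values of these 3 genes still do not settle the question. The rise of Kdm5d is close to the 0.60 (log2) by which the BioB, BioC and BioD controls were higher. Whether related X-linked genes account for the rise was not tested.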

How the results depend on the processing

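Tests with an offset of 16, values raised to background, spike scaling and the trend and robust prior combined with the block or a left-out array were chosen after the result was seen.

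Counts of genes higher and lower moved with the settings: 1955 and 1230 (4729 probe sets) without probe sets below the 30th percentile of level, 2820 and 1978 (9079 probe sets) without those below the 50th, 3156 and 2251 (10273 probe sets) with the trend and robust prior, 2451 and 1567 (7498 probe sets) with an offset of 16, and 2157 and 1309 (7317 probe sets) with values raised to background. Low values are noisy, with a median replicate SD of 1.31 in the dimmest 25% of genes. Spike scaling gave 650 and 2456, a larger rise in lower genes than any of the settings above. At an adjusted p below 0.01, with the mean of a gene's probe sets, or with the replicate block, limma called 0 genes higher and 0 lower, and leaving out each array gave 0 to 0 for both, with fewer residual degrees of freedom in the latter and in the block. Unadjusted, 3882 to 4012 genes lay below 0.05 without an array, 4465 with the block, 4457 with the mean of probe sets and 5558 in the main design. Causes other than fewer samples were not tested. With an array left out, the lone array is assumed to vary like the other group.

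Replicate numbers share no stated origin, and the deviations of same-numbered arrays correlated at 0.012 over all genes and 0.25 over intense ones. With the trend and robust prior, the block gave 3469 and 2554 genes. The mean of probe sets turned Ikzf2 to -0.92. This came from a dim probe set (-3.93) at or below background on both tumour arrays, while the others gave 1.21 and -0.03. With camera's correlation fixed at 0.01, other settings left the number of lists called between 10 and 17, against 13, and 0 chromosomes, while 0 lists passed with an estimated correlation. Over lists and settings, 481 results stayed on their side of the threshold, 11 became stronger and 16 weaker. For named genes 1062 stayed, 28 became stronger, 700 weaker and 1 reversed. Signal over background limits the result, with 4336 genes at or below background on all arrays in every probe set.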

Other observations

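The scan of gene families was chosen after the data were seen.

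Genes were grouped into 349 families by the letters that open their symbols, and each was tested in both directions by Fisher's exact test for an excess of genes called with the trend and robust prior, among 10574 genes above background on at least 2 arrays. Of 698 tests, 0 passed after Benjamini-Hochberg adjustment (smallest adjusted p = 0.298) and 33 lay below 0.05 unadjusted. Among the families with the smallest unadjusted p were the Snhg genes, hosts of small nucleolar RNAs, with 9 of 13 higher and a median log2 fold change of 1.12 (adjusted p = 0.298). The Trav family, variable segments of the TCR alpha chain, had 4 of 5 lower and a median of -2.24 (adjusted p = 0.414). The Armcx family of the X chromosome had 4 of 6 lower and a median of -3.61 (adjusted p = 0.657). These fail the correction and are given as values only.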
